A study of Mus musculus with 6 samples.

How the data were processed

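Total RNA from isolated intestinal crypts of 6 mice was measured on Affymetrix mouse gene arrays, 1 array per mouse. Per the labels' protocols, the washed intestine was treated with EDTA to release crypts, which were not cultured, and RNA was purified with a Qiagen kit and labelled with biotin. The groups, control and YAP transgenic with 3 mice each, were taken from the sample titles. Doxycycline was given for 2 days per the series' design text, which does not say whether controls received it or which transgenes they carried. The titles number the controls as mouse 1 to 3 and the transgenic samples as YAP Tg 1 to 3, and each sample was taken as a separate mouse.

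The authors deposited a table of log2 signals for 35556 probe sets per array, made with Affymetrix Expression Console version 1.1 per the submitters' processing notes. The log2 scale was read from the deposited values, which lie between 1.99 and 14.4. The background correction, normalization and summary of probes into probe sets are not given in the sources used here, and scanner files were not used here. Median signals of all probe sets were 6.19 to 6.32, so the arrays had been brought to a common level. A normalization that assumes most genes do not change hides any change common to all genes.

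The 6617 probe sets numbered below the first one named in the platform annotation were taken to be array controls, from their numbers alone, and left out. Of the remaining 28939 probe sets, 21789 had 1 gene symbol, 1621 had several and 5529 were not listed. Genes were named only from probe sets with 1 symbol, and 21698 of these were matched by Entrez identifier to a RefSeq gene table of the mouse assembly GRCm38.p6, which changed 0 symbols. The array's own build is not given in the sources used here, so that table served only for names and the order of neighbouring genes. For the 19938 genes the probe set with the highest mean over the 6 arrays was used; of 999 genes with several probe sets, 96 were called by some and not others and 0 were called in opposite directions. Of 501 gene list members fixed before the data were examined, 453 were measured here and the others were not analysed here. Older symbols in the lists were read as Ccn1, Ccn2, Slc51a, Slc51b, Clca1, Jchain, Adgre1 and Kdm5d where those are the current names.

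Differences were tested on the log2 values with limma version 3.58.1 in R version 4.3.3 (lmFit and eBayes, two-sided, no covariate), and p-values were adjusted by Benjamini and Hochberg over all genes at a threshold of 0.05. Every log2 change is transgenic minus control. Gene lists were tested with camera from limma with a preset correlation of 0.01, adjusted over 36 lists, and again with the correlation estimated per list and with fry. In simulated data built from the 19938 genes of this comparison, 75% of genes changed by a log2 of 1 and 96% of those changed by a log2 of 2 were recovered, and 2.29% of calls were false. There, 100 genes were changed by each amount, noise was drawn independently per gene and both groups had the same spread. In the real arrays more genes were called, genes moved together and transgenic mice varied more. These shares therefore need not hold for the real comparison.

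Genes named in the text follow a rule fixed before the data were examined. It takes the 10 largest increases and 10 largest decreases among genes past the test whose group values do not overlap, leaving out clone-like symbols, together with 14 genes chosen for crypt and YAP biology. It adds, per list, up to 4 members with the smallest p among those past the test or up to 2 others. Genes named outside the rule are marked as such in the account of the comparison, and in the additional observations all genes beyond these were named after their values were seen. The alternatives tried were leaving out each mouse, the replicate number as a block, quantile normalization, median centring, filters on signal, a trended and robust prior, array weights, averaging of probe sets, other thresholds and other list tests.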

Results

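Gene expression was measured in intestinal crypts, the epithelial pits that hold the stem and progenitor cells of the gut lining, from 3 control and 3 YAP transgenic mice. By the series title the transgene encodes YAP-S127A, a form of the transcriptional coactivator YAP that lacks a serine through which the Hippo kinases inhibit it. It was switched on in the intestinal epithelium through Villin-rtTA and doxycycline, which was given for 2 days before the crypts were taken. Each mouse gave 1 array. The deposited table holds log2 signals of 35556 probe sets per array, and 19938 genes were tested. The median log2 signal of these genes was between 6.74 and 6.79 on every array. Their lower quartile was 5.41 to 5.47 on control arrays and 5.52, 5.43 and 5.57 on transgenic arrays 1, 2 and 3. Upper quartiles were 8.60 to 8.69 on control arrays and 8.45, 8.66 and 8.49 on the transgenic arrays. Signals of transgenic mice 1 and 3 were thus spread less widely, and those of mouse 2 were like the controls. The number of arrays, 3 per group, limits the precision of each value below.

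The control arrays were closer to each other than the transgenic arrays were. Across genes, Pearson's r was 0.996 to 0.997 between control arrays, 0.978 to 0.989 between transgenic arrays and 0.945 to 0.975 between the groups; genes are not independent replicates. The first principal component held 75.0% of the variance and separated the groups. On it transgenic mouse 2 lay nearest the controls, at 18.8, against 58.9 and 34.8 for transgenic mice 1 and 3. The controls stood at -40.4 to -35.3. The second component held 13.4%. On it transgenic mouse 2 stood at -36.1, against 11.7 and 12.5 for the other transgenic mice and 2.08 to 6.36 for the controls. The median of the 6617 probe sets numbered below the named ones, taken to be array controls, was 4.97 ± 0.0130 (SD, n = 3) in control and 5.17 ± 0.150 in transgenic arrays, a difference of 0.196 on the log2 scale.

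The question of the comparison was which genes of the crypt change after 2 days of activated YAP. Whether the control mice received doxycycline is not stated, so an effect of the drug cannot be told apart from that of YAP. In the transgenic crypts 8 of 22 YAP/TEAD targets, 8 of 15 genes of fetal-like, regenerating epithelium and 11 of 12 markers of T cells and intraepithelial lymphocytes rose. In turn, 16 of 23 markers of Lgr5 stem cells, 8 of 19 Wnt targets and 8 of 13 goblet cell genes fell. With an estimated correlation none of these lists kept its shift (camera adjusted p = 0.316 for each), though few lists could pass that test with 3 arrays per group. By limma's test at an adjusted p below 0.05, 1495 genes were higher and 1336 lower in transgenic crypts, 14.2% of those tested. Of these, 519 rose and 468 fell at least 2-fold, and 104 rose and 103 fell at least 4-fold. All 3 transgenic values lay above all 3 control values for 3299 genes and below them for 3395, which is 16.5% and 17.0% of genes, where chance gives 10% for both directions together. The counts moved with the arrays used. Without control mouse 1, 2 or 3 they were 674 higher and 368 lower, 728 and 416, or 668 and 461. Without transgenic mouse 1, 2 or 3 they were 1140 higher and 888 lower, 2802 and 3889, or 1068 and 811.

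Yap1 was not higher on its probe set in the transgenic crypts. It stood at 9.41 ± 0.09 (SD, n = 3) in control and 9.17 ± 0.16 in transgenic crypts, a log2 change of -0.24 (SE 0.10, limma's adjusted p = 0.184). Whether this probe set covers the transgene's transcript is not given in the sources used here, so Yap1 does not check the labels. Of the YAP/TEAD targets named before the data were examined, Ccn1, a secreted matricellular protein, rose from 6.18 ± 0.03 to 10.67 ± 0.11. Its log2 change of 4.49 (SE 0.08, limma's adjusted p = 2.1e-05) had the smallest adjusted p of all genes tested. Ccn2, of the same family, rose by 1.65 (SE 0.14, limma's adjusted p = 0.00159). Ankrd1 had a low signal in both groups, 4.86 in control and 4.94 in transgenic crypts, and did not pass the test (limma's adjusted p = 0.405). Its value was the same, 4.945, on all 3 transgenic arrays. Both means lay below the medians of the probe sets taken to be array controls (4.97 and 5.17), so this probe set says little about Ankrd1.

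**Figure D1:**
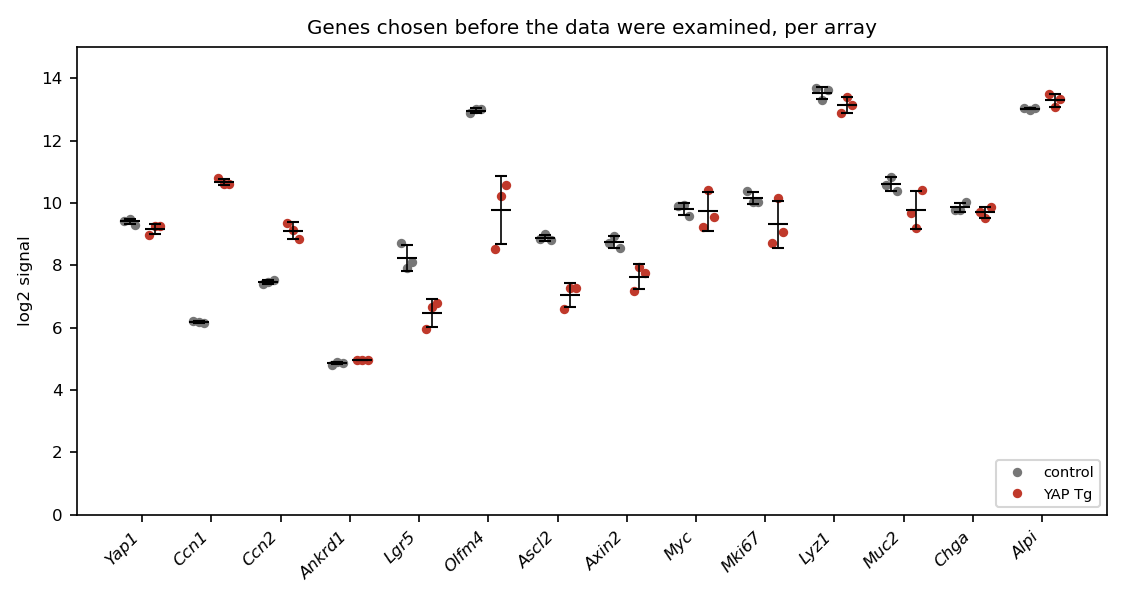
Log2 signal per array (points; 3 control and 3 transgenic mice) of the genes fixed before the data were examined, with the group mean (dash) and SD (bars). Ccn1 went from 6.18 to 10.67 and Olfm4 from 12.96 to 9.77, while Yap1 differed by -0.24.

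The named genes with the largest measured increases were Ppef1, a calcium-binding protein phosphatase (log2 change 5.32), Gml (4.95), Ly6f (4.83), Edn1, which encodes endothelin 1 (4.77), Serpinb9b (4.56), Ccn1 (4.49), the lysyl oxidase relative Loxl4 (4.32), Wwc2, a relative of the Hippo component Kibra (4.10), the LIM-domain protein Ajuba (3.94) and Psca (3.91). Gml, Ly6f and Psca belong to the Ly6 family of membrane-anchored proteins. The largest measured decreases were in the carboxylesterase Ces1f (-5.43), the lactate transporter Slc5a12 (-5.16), the aldo-keto reductases Akr1c19 (-4.95) and Akr1c14 (-4.79), the cytochromes P450 Cyp3a25 (-4.88) and Cyp2c55 (-4.22), the glutathione transferase Gstm3 (-4.85), the chloride-bicarbonate exchanger Slc26a3 (-4.38), the hydroxysteroid dehydrogenase Hsd17b6 (-4.08) and the dicarboxylate transporter Slc13a2 (-3.89). The control means of Ppef1 and Ly6f and the transgenic means of Ces1f, Akr1c14 and Cyp2c55 lay below the median of the probe sets taken to be array controls (4.97 in control and 5.17 in transgenic arrays). These 5 changes, if that median marks background, are lower bounds, and the order of the genes is not exact. Standard errors ran from 0.08 to 0.74 and limma's adjusted p from 2.1e-05 to 0.0122. Several belong to families of near-identical genes, among which an array can cross-hybridise. The call of Serpinb9b was lost without control mouse 1, 2 or 3, with an adjusted p of up to 0.0662.

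**Figure D2:**
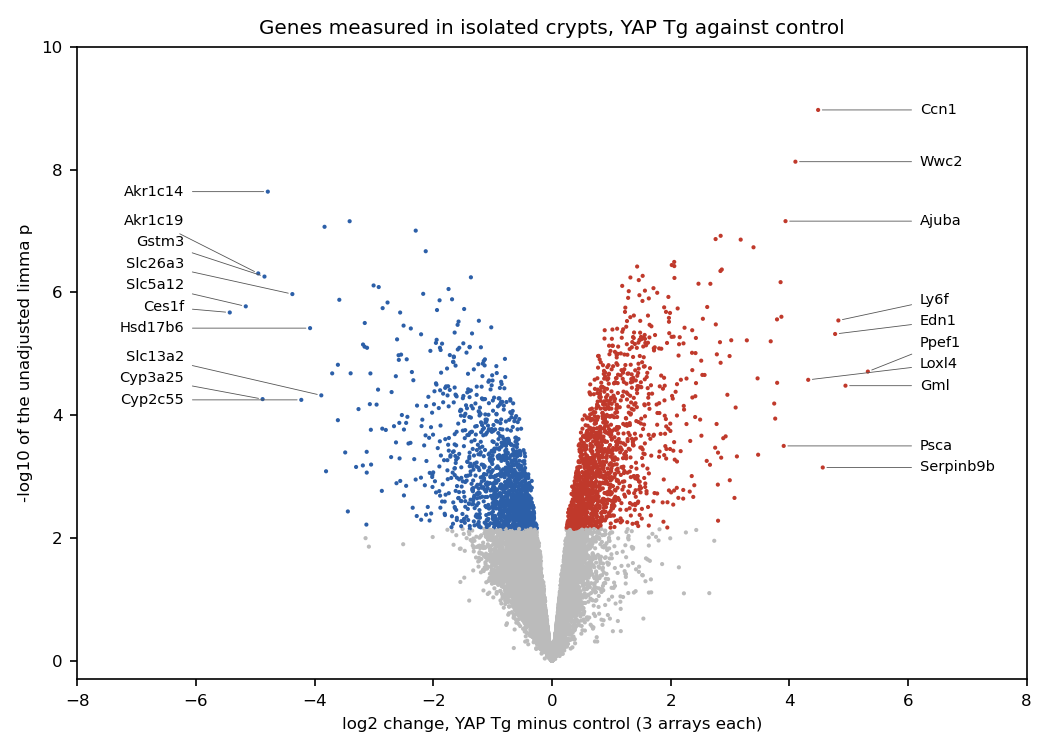
Log2 change (transgenic minus control, 3 arrays each) against -log10 of limma's unadjusted p for each gene. Red points (1495) were higher and blue points (1336) lower at an adjusted p below 0.05, and the 10 largest measured changes in each direction under the naming rule are labelled, from Ces1f at -5.43 to Ppef1 at 5.32.

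Of 36 gene lists fixed before the data were examined, 8 were shifted upward and 10 downward relative to other genes by camera with a preset correlation of 0.01. None of these kept its call when the correlation within each list was estimated. That setting tests against the few residual degrees of freedom that 3 arrays per group leave, so few lists could pass it. The EGF receptor list, with an estimated correlation of -0.05, also had camera's adjusted p = 0.316 there. The loss of calls therefore does not show that correlation within the lists accounts for the shifts. The adjusted p under that setting is given with each called list below. By fry, which asks whether a list's genes moved on balance one way, 9 lists were higher and 7 lower.

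Targets and parts of the Hippo pathway rose in part. Of 22 YAP/TEAD targets, 8 rose and none fell (9 and 0 adjusted over the list alone), with a median log2 change of 0.34 (camera adjusted p = 5.2e-07, and adjusted p = 0.316 with an estimated correlation). Beside Ccn1 and Ccn2 they included Amotl2 (1.72) and Lats2 (1.65), both inhibitors of YAP, which the Hippo list also holds. Of 21 Hippo components, 6 rose and none fell, and 6 and 0 adjusted over the list alone (median 0.13, camera adjusted p = 0.0198, and adjusted p = 0.323 with an estimated correlation). They included Tead1, a DNA-binding partner of YAP (2.05, SE 0.14), Wwc1, which encodes Kibra (2.02, SE 0.09), and, named after its value was seen, the YAP paralog Wwtr1 (1.90). The shift of the Hippo list was not called without transgenic mouse 2 or with array weights, and without that mouse 1 component was lower.

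Genes of fetal-like and regenerating epithelium rose. Of 15 measured, 8 were higher and none lower (11 and 0 adjusted over the list alone), with a median of 1.58 (camera adjusted p = 2.0e-07, and adjusted p = 0.316 with an estimated correlation). Anxa3 rose by 3.47 (SE 0.32), Krt7, a keratin of simple ductal epithelia, by 2.86 (SE 0.13), the alarmin cytokine Il33 by 2.84 (SE 0.13) and Phlda1 by 2.36 (SE 0.18). Limma's adjusted p for these genes was between 0.000482 and 0.00191.

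Stem cell markers fell. Of 23 genes of the Lgr5 stem cell signature, 16 fell and 1 rose (17 and 2 adjusted over the list alone), with a median of -1.03 (camera adjusted p = 2.9e-08, and adjusted p = 0.316 with an estimated correlation). Olfm4, the secreted glycoprotein that marks these cells, fell from 12.96 ± 0.08 to 9.77 ± 1.09, a change of -3.19 (SE 0.51, limma's adjusted p = 0.0116). Lgr5 itself changed by -1.76 (SE 0.29, limma's adjusted p = 0.0130), the stem cell transcription factor Ascl2 by -1.83 (SE 0.19, adjusted p = 0.00299), the urea transporter Slc14a1 by -2.30 (SE 0.08), the water channel Aqp4 by -1.99 (SE 0.21) and Gkn3 by -1.66 (SE 0.18). The gene that rose was Rassf5 (0.45, named after its value was seen). The 16 became 8, 8 or 7 without control mouse 1, 2 or 3 and 10 without transgenic mouse 3, and no stem cell gene was called higher with any 1 control or transgenic mouse 1 left out, and 2 were without transgenic mouse 2. The call of Olfm4 was lost without control mouse 1, 2 or 3 (adjusted p up to 0.0637) and that of Lgr5 without control mouse 3 (0.0591).

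Wnt/beta-catenin targets fell in part. Of 19, 8 fell and none rose, the same numbers adjusted over the list alone (median -0.42, camera adjusted p = 3.5e-04, and adjusted p = 0.316 with an estimated correlation). The 2 lists share 8 measured genes, and 6 of the 8 that fell also stand in the stem cell signature. Beside Lgr5 and Ascl2, Fermt1 changed by -1.50 (SE 0.27), the negative feedback gene Axin2 by -1.12 (SE 0.21, limma's adjusted p = 0.0208) and the receptor Ephb3 by -0.73 (SE 0.10). Myc, another Wnt target, stood at 9.81 ± 0.19 in control and 9.73 ± 0.62 in transgenic crypts (limma's adjusted p = 0.883). The 8 became 3, 3 or 2 without control mouse 1, 2 or 3 and 3 without transgenic mouse 3, and Axin2 and Fermt1 were not called in any of these settings. Of 6 markers of quiescent cells at the position above the crypt base, Hopx (-0.86) and Sox4 (-0.97) fell and none rose (3 and 0 adjusted over the list alone; camera adjusted p = 0.0156, and adjusted p = 0.316 with an estimated correlation). Neither was called without control mouse 1, 2 or 3 or transgenic mouse 3, and the shift was lost among probe sets above the median signal.

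Genes of the cell cycle differed between the transgenic mice. None of 24 passed limma's test, with all 3 mice or adjusted over the list alone, although the median was -0.73 (camera adjusted p = 3.5e-04, adjusted p = 0.689 with an estimated correlation, and adjusted p = 0.314 by fry). The list's median difference from the control mean was -1.24 in transgenic mouse 1, 0.06 in mouse 2 and -0.91 in mouse 3. Without transgenic mouse 2, which stood apart on the second component and lay nearest the controls on the first, 22 of the 24 were lower. The proliferation marker Mki67 stood at 10.15 ± 0.19 in control and 9.32 ± 0.76 in transgenic crypts, a log2 difference of -0.84 (limma's adjusted p = 0.185). Of 13 genes of mitochondrial translation, 1 was lower with all mice, Mrpl15 (-0.54), and 10 were lower without transgenic mouse 2. This list had a median of -0.54 (camera adjusted p = 0.00543, adjusted p = 0.665 with an estimated correlation, and 0.271 by fry) and 0 members called adjusted over the list alone. Its shift was lost without transgenic mouse 3 and among probe sets above the median signal, and Mrpl15 was called in no setting that left out a control, transgenic mouse 1 or transgenic mouse 3.

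**Figure D3:**
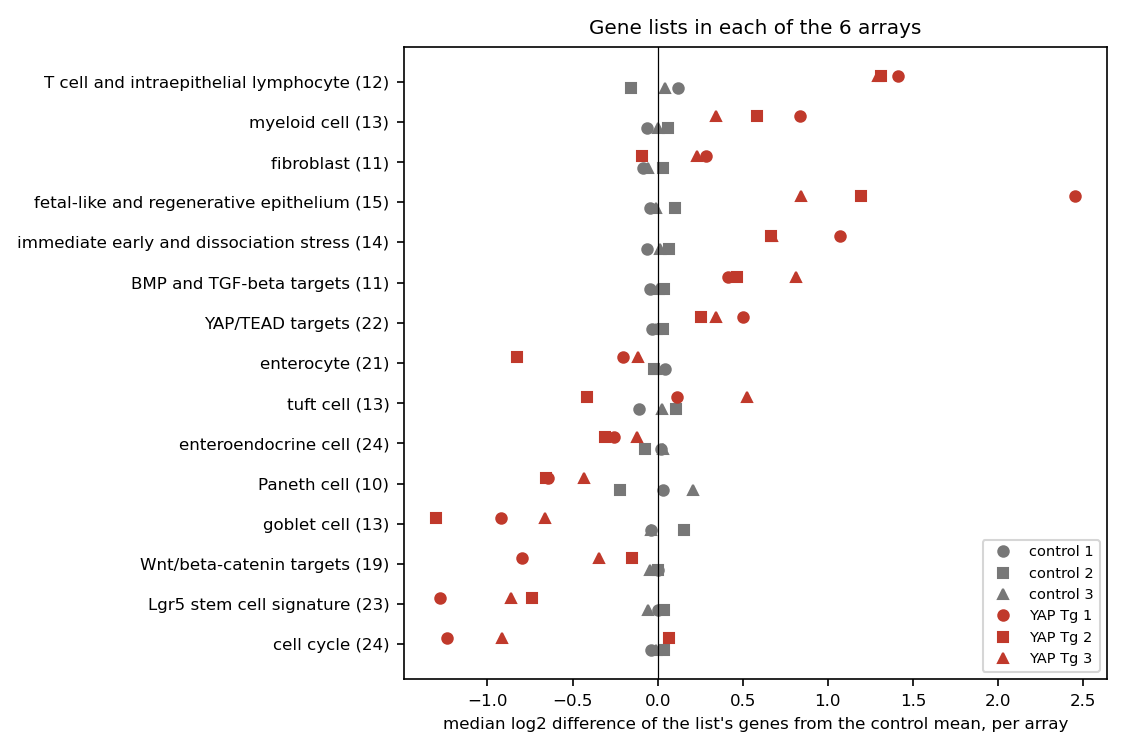
Median log2 difference of each list's genes from the control mean, per array (grey, 3 control mice; red, 3 transgenic mice; number of genes in brackets). The T cell list lies between 1.29 and 1.41 in the transgenic mice, and the cell cycle list at -1.24, 0.06 and -0.91.

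Goblet cell genes fell as a group. Of 13, 8 fell and none rose (9 and 0 adjusted over the list alone), with a median of -0.93 (camera adjusted p = 5.2e-07, and adjusted p = 0.316 with an estimated correlation). Agr2, a disulfide isomerase needed to make mucin, changed by -2.21 (SE 0.15, limma's adjusted p = 0.000988), the glycosyltransferase Galnt12 by -1.43 (SE 0.14), the goblet cell transcription factor Spdef by -1.05 (SE 0.16) and Ramp1 by -0.77 (SE 0.08). Atoh1, the transcription factor of the secretory lineage, changed by -1.95 and was named after its value was seen. The mucin Muc2 stood at 10.60 ± 0.22 in control and 9.77 ± 0.61 in transgenic crypts (limma's adjusted p = 0.130). The 8 became 4 without control mouse 1, 2 or 3, and Spdef was not called without control mouse 3 (adjusted p = 0.0511).

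Of 10 Paneth cell genes, 4 fell and none rose (5 and 0 adjusted over the list alone; median -0.52, camera adjusted p = 5.3e-04, and adjusted p = 0.341 with an estimated correlation). They were the phospholipase Pla2g2a (-1.30, SE 0.18), Habp2 (-1.08), Clps (-0.72) and Ang4 (-0.65), while Lyz1, the Paneth cell lysozyme, differed by -0.39 (limma's adjusted p = 0.158). Only 1 was called without control mouse 1 or 3 and 2 without control mouse 2 or transgenic mouse 1 or 3. Of 24 enteroendocrine genes, 3 fell and 1 rose (5 and 1 adjusted over the list alone; median -0.18, camera adjusted p = 0.00562, and adjusted p = 0.341 with an estimated correlation). Neurog3, the transcription factor that specifies these cells, changed by -1.88 (SE 0.14, limma's adjusted p = 0.00111), Rfx6 by -0.83 and Chgb by -0.37, and the hormone gene Cck rose by 0.45. Chga differed by -0.16 (adjusted p = 0.419). Without control mouse 1 or 3 just 1 gene was lower, and without transgenic mouse 2 there were 6 lower and 4 higher. Cck lost its call with any array other than transgenic mouse 2 left out. The list's shift was lost without transgenic mouse 2, among probe sets above the median signal and with array weights. None of 13 tuft cell genes passed the test (camera adjusted p = 0.667), while without transgenic mouse 2 there were 5 higher and the shift passed (0.0390).

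Enterocyte genes, which mark the absorptive cells of the villus, moved both ways. Of 21, 6 fell and 2 rose (9 and 2 adjusted over the list alone), with a median of -0.17 (camera adjusted p = 0.0353, adjusted p = 0.713 with an estimated correlation, and 0.223 by fry). The fatty acid binding proteins Fabp2 (-1.49, SE 0.11) and Fabp1 (-1.74, SE 0.25) and the meprin Mep1a (-2.46, SE 0.45) fell, and Krt20, a keratin of differentiated cells, rose by 1.09 (SE 0.12, limma's adjusted p = 0.00335). The alkaline phosphatase Alpi differed by 0.27 (adjusted p = 0.165). The 6 became 2, 2 or 1 without control mouse 1, 2 or 3 and 3 without transgenic mouse 1, and the 2 that rose became 1 with any 1 control or transgenic mouse 3 left out. The call of Fabp1 was lost without control mouse 3 and that of Mep1a with any 1 control left out. The shift was lost under quantile normalization, with array weights, among probe sets above the median signal and without control mouse 1 or transgenic mouse 2. Of 12 genes of fatty acid oxidation, Acaa2 (-1.17), Cpt1a (-1.02) and Ehhadh (-1.21) fell and none rose (7 and 1 adjusted over the list alone; camera adjusted p = 0.0293, and adjusted p = 0.316 with an estimated correlation). They became 1 without control mouse 1 or 2, and Ehhadh was not called without control mouse 3 or transgenic mouse 1 either; 1 gene was higher without transgenic mouse 2. This shift was lost under quantile normalization, with array weights, among probe sets above the median signal and without transgenic mouse 2 or 3. Of 9 markers of the proximal intestine, 2 fell and 1, the iron exporter Slc40a1 (1.99), rose (4 and 2 adjusted over the list alone); 1 was lower without control mouse 1 or 3. Of 10 of the distal intestine, the bile acid transporter subunit Slc51b rose by 1.43 and Ang4 fell (2 higher and 1 lower adjusted over the list alone); without transgenic mouse 1 or 2 there were 2 higher, and Ang4 lost its call with any array other than transgenic mouse 2 left out. Neither position list was shifted (camera adjusted p = 0.125 and 0.531), although the proximal list passed without transgenic mouse 3.

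Among signalling lists, Notch genes moved both ways. Of 14, 4 rose and 4 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.492). The ligand Dll4 changed by -1.39 (SE 0.10), the feedback regulator Nrarp by -1.87 (SE 0.28), the ligand Jag2 by 0.99 (SE 0.15) and Dtx1 by 0.61 (SE 0.08). Only 1 was higher and 1 lower without control mouse 1 or 2, 2 were higher without control mouse 3 and 2 lower without transgenic mouse 3. Of 11 BMP and TGF-beta targets, 5 rose and none fell, and 6 rose and 1 fell adjusted over the list alone (median 0.50, camera adjusted p = 3.6e-04, and adjusted p = 0.316 with an estimated correlation). They included the inhibitory Smad7 (1.84, SE 0.14) and the helix-loop-helix inhibitors Id3 (1.68, SE 0.11), Id1 (1.35, SE 0.10) and Id2 (0.94, SE 0.12). Of 11 EGF receptor genes, the ligands Hbegf (1.89, SE 0.11) and Tgfa (0.67, SE 0.07) and the receptor Egfr (1.40, SE 0.30) rose and none fell (4 and 1 adjusted over the list alone). That list's shift did not pass with camera (adjusted p = 0.0614) but passed by fry (0.00276), with the replicate block, with either scaling, above the median signal and without control mouse 1 or 2 or transgenic mouse 1. Egfr was not called with any 1 control or transgenic mouse 3 left out, and 1 gene was lower without transgenic mouse 2.

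Of 14 immediate early genes, which respond to growth signals and also to tissue dissociation, 8 rose and none fell (10 and 0 adjusted over the list alone; median 0.78, camera adjusted p = 7.3e-06, and adjusted p = 0.316 with an estimated correlation). Atf3 rose by 2.22 (SE 0.24), the phosphatase Dusp1 by 2.02 (SE 0.21), Klf6 by 1.41 (SE 0.15) and Fos by 1.38 (SE 0.14). Of 15 p53 targets, 4 rose, among them Perp (0.92), and Sesn2 (-0.40, named after its value was seen) fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.0968, and 0.00276 by fry). The shift also passed among probe sets above the median signal. Sesn2 was not called without control mouse 1 or 2 or transgenic mouse 1 or 3, and the 4 became 2 without control mouse 2, 1 without control mouse 3 and 8, with 2 lower, without transgenic mouse 2. Of 15 genes of the unfolded protein response, Atf3 and Chac1 (0.69) rose and Herpud1 (-1.12) and Xbp1 (-0.51) fell, the same numbers adjusted over the list alone (camera adjusted p = 0.680). Chac1 was not called without control mouse 2 or 3 or transgenic mouse 3, nor Xbp1 with any 1 control left out, and 5 rose and 5 fell without transgenic mouse 2. Of 18 antimicrobial and inflammatory genes, Duox2 (2.80, SE 0.67) and Saa3 (0.33) rose and none fell, the same numbers adjusted over the list alone (camera adjusted p = 0.00582, adjusted p = 0.341 with an estimated correlation, and 0.0536 by fry). None of this list was called without control mouse 1 or transgenic mouse 1, and 1 was called without control mouse 3 or under quantile normalization. Neither Duox2 nor Saa3 was called without control mouse 3 or transgenic mouse 3, nor Saa3 without control mouse 2. None of 15 interferon response genes (camera adjusted p = 0.125) or 13 of cholesterol synthesis (0.748) passed. Of the interferon genes 1 was higher without transgenic mouse 2 or 3, and their shift passed without control mouse 2 or transgenic mouse 3. Of the cholesterol genes 3 were lower without transgenic mouse 2 and 1 higher without mouse 1.

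Markers of T cells and intraepithelial lymphocytes rose in the transgenic crypts. Of 12, 11 rose and none fell (12 and 0 adjusted over the list alone), with a median of 1.35 (camera adjusted p = 1.6e-11, and adjusted p = 0.316 with an estimated correlation). The list's median was 1.41, 1.31 and 1.29 in the 3 transgenic mice. The T cell receptor subunit Cd3d rose by 1.59 (SE 0.12), the coreceptor Cd8a by 1.46 (SE 0.11), Cd7 by 1.35 (SE 0.10) and the leukocyte phosphatase Ptprc by 1.32 (SE 0.06), each with limma's adjusted p between 0.000482 and 0.00106. Of 13 myeloid genes, 7 rose and 1 fell, the same numbers adjusted over the list alone (median 0.61, camera adjusted p = 0.00167, and adjusted p = 0.316 with an estimated correlation). Tyrobp, an adapter of myeloid and natural killer cells, rose by 1.71 (SE 0.22), the complement gene C1qb by 1.48 (SE 0.26) and the macrophage receptor Csf1r by 0.85 (SE 0.10). The 7 became 3, 4 or 2 without control mouse 1, 2 or 3 and 4 without transgenic mouse 1, and C1qb was not called without control mouse 1 or 3. The gene that fell was Itgam (-0.43, named after its value was seen), which was not called without control mouse 1 or 2 or transgenic mouse 1 or 3, under quantile normalization or with each array centred; 2 were lower without transgenic mouse 2.

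Markers of other cell types that a crypt preparation can hold did not pass limma's test. This was so for 8 genes of B and plasma cells, 11 of fibroblasts, 8 of smooth muscle, 10 of endothelium, 6 of neurons and glia and 7 of pancreatic acinar cells, with all arrays and adjusted over each list alone. The same held for 6 genes of MHC class II and 4 sex-linked genes, which were not fixed as markers of another cell type. Over all of these lists the medians lay between -0.06 and 0.72, and camera's adjusted p between 0.262 and 0.916. Without transgenic mouse 2, 2 fibroblast, 1 smooth muscle and 1 acinar gene were higher and 3 MHC class II and 1 smooth muscle gene lower, and the shifts of the acinar and MHC class II lists passed. Without transgenic mouse 3, 1 fibroblast gene was lower. Of 5 adipocyte genes 1, Cidec, rose (1.31, SE 0.24, also adjusted over the list alone; camera adjusted p = 0.185), and it lost its call with any array other than transgenic mouse 2 left out.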

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

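The tests of background signal and of villus tissue were chosen after the result was seen; the others were written before it. The arrays' control-numbered probe sets, outside the comparison, had a median signal 0.1961 higher on the log2 scale in transgenic than in control arrays, and every transgenic array lay above every control array. Among probe sets that the annotation used here does not list, 191 passed limma's test, 91 higher and 100 lower in transgenic crypts.

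Markers of T cells and intraepithelial lymphocytes rose by a median of 1.35 in transgenic crypts. Carry-over of lamina propria or a smaller epithelial share would raise fibroblast, smooth muscle and endothelial markers alike. Their median change was 0.07599 over 29 genes and 0.13 over the 15 with a control signal of at least 6. The mean over the 29 lay 1.22 below that of the T cell list (SE 0.105 over genes). Such carry-over would also raise B and plasma cell and myeloid markers. The median of the former was 0.11 with none called. Their changes ran from -0.33 for Ms4a1, dim at 4.98 in control crypts, to 1.00 for Jchain (limma's adjusted p = 0.194). The median of the myeloid markers was 0.61 with 7 higher and 1 lower. These values argue against carry-over of fibroblast, smooth muscle and endothelial tissue, while carry-over of immune cells alone stays open. A higher background is also argued against. Genes of the same mean signal changed by -0.06841 on average, 1.35 below the list (SE 0.105 over genes). Both SE measure the spread between genes on the same arrays, not between mice. Per mouse the list's median lay between 1.29 and 1.41 in transgenic and between -0.15 and 0.12 in control arrays. More villus tissue, where most such lymphocytes reside, cannot be told apart from the transgene's own effect on enterocyte genes, whose median was -0.1694 with 6 lower and 2 higher. No list gene is in another list, and which of them epithelium expresses was not measured. The cause of the rise of 7 myeloid genes was not tested. More lymphocytes in the transgenic epithelium may be a further explanation, as an untested hypothesis.

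Dbp, a gene under direct control of the circadian clock, was lower in transgenic crypts by a log2 of -3.06 (SE 0.27, limma's adjusted p = 0.00176, below all controls in 3 of 3 mice). If the groups had been killed at different times of day, other genes of the same phase would fall too. Their mean change was -0.9919 (SE 0.280 over genes, not mice), with 6 of 8 past the test and lower. Among them was Ciart (-2.61), while Nr1d1 differed by 0.01 (limma's adjusted p = 0.992). Of 4 genes of opposite phase 1, Arntl, passed and was higher (1.06, limma's adjusted p = 0.0203), and their mean was 0.25 (SE 0.291 over genes). A difference in time of death is therefore a candidate explanation, and an effect of the transgene on the clock stays open and was not tested. Without control mouse 1, 2 or 3 the 6 became 4, and Arntl was not called with any 1 control or transgenic mouse 1 left out.

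Genes next to each other on a chromosome were often called in the same direction, with 25 runs of at least 3 higher and 15 lower, such as Ces1c to Ces1g and Ugt2b35 to Ugt2a3. Among neighbours whose symbols share a stem, 69 pairs were called alike, against 9.45 on average and at most 23 in 1000 permutations of the calls among genes of like signal. Cross-hybridisation between paralogs of 1 family is argued against as the whole cause, since 299 pairs with different stems were called alike, against 220 on average and at most 262. Pairs with different stems do not test it among pairs that share a stem, so it stays open for runs such as Ces1c to Ces1g. Stems miss some paralogs, such as Fos, Jdp2 and Batf, so part of the excess may still come from shared sequence. Shared regulation of neighbours stays open and was not tested.

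With 3 mice against 3, the 6 arrays make 10 splits, too few for a share under 0.05. The real split called 2831 genes and 2867 probe sets, and the highest of the other splits called 0 of each, so that 1 of the 10 gave as many. Each of the other splits mixed control and transgenic arrays, so the difference between the groups widened the spread within them. Their calls therefore do not show what chance alone gives.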

How the results depend on the processing

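All alternatives below were planned before the data were examined, and the arrays' signal over background limits dim genes. No gene called with all mice took the opposite call under any of the gene-level alternatives. Of 128 named genes 96 were called, and 0 of these turned in direction, though only 90 of them were tested above the median signal. Of the 96, 27, 24 or 29 lost their call without control mouse 1, 2 or 3, 9, 0 or 15 without transgenic mouse 1, 2 or 3 and 11 with the replicate block. With either scaling, the filter above the median signal, the trended prior, array weights or averaging of probe sets, 0 to 3 lost it. The other thresholds and the filter at a mean log2 of 6 were not applied to the named genes. Leaving out 1 mouse gave 668 to 2802 genes higher and 368 to 3889 lower, 560 to 3382 probe sets higher and 283 to 5077 lower, 7 to 17 stem cell genes lower and 0 to 2 higher, 2 to 10 Wnt targets lower and 0 to 22 cell cycle genes lower. Fewer arrays were tested there, and the high counts came without transgenic mouse 2. The sample titles do not say whether the replicate numbers pair the mice. Deviations of same-numbered mice correlated at -0.131, 0.0124 and 0.0983 across genes, which gives no sign of pairing but cannot exclude it. With the replicate block, 975 genes were higher and 727 lower, 833 probe sets higher and 558 lower, 4 Wnt targets lower, and 10 stem cell genes lower and 0 higher; not every array correlated best with its own number.

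With array weights, 2459 genes were higher and 3481 lower (41.4% higher, against 52.8%), 2630 probe sets higher and 4302 lower, 2 stem cell genes higher and 20 cell cycle genes lower. At an adjusted p below 0.10, 2101 genes and 2380 probe sets were lower. Averaging probe sets gave 2 stem cell genes higher. Quantile normalization and the filter above the median signal each gave 1 cell cycle gene lower, and that filter 5 lists lower. An estimated correlation left 0 lists higher and 0 lower, with an adjusted p of 0.3159 for the YAP/TEAD, fetal-like, Wnt, stem cell and T cell lists and 0.6891 for the cell cycle list, for which fry gave 0.3143. With an estimated correlation few lists could pass on so few arrays, so that loss does not show that the lists did not shift. The cause was not tested in any of these alternatives.

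Results that reversed had not passed the test with all mice, and the cause was not tested. By adjusted p of the shift, these were the unfolded protein response (0.9528), MHC class II (0.9219), cholesterol (0.9219) and endothelial (0.9375) lists under quantile normalization, the first 3 of them above the median signal (0.8924, 0.9402 and 0.8924), and the sex-linked list by fry (0.9893). Over the settings that left out 1 mouse, in some of which the direction turned, adjusted p ran from 0.02135 to 0.9258 for MHC class II, 0.1386 to 0.9336 for cholesterol, 0.7379 to 0.971 for the sex-linked, 0.03904 to 0.8908 for the tuft and 0.4298 to 0.8647 for the unfolded protein response list. Log2 changes ran from -0.4255 to 0.1695 for Myc, -0.06967 to 0.2645 for H2-Ab1, -0.2359 to 0.03605 for Cd74 and -0.001125 to 0.1037 for Kdm5d. Cd74 gave 0.04008 under quantile normalization and H2-Ab1 -0.01246 with array weights.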

Other observations

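Genes were also grouped by the letters that open their symbols, a grouping chosen after the data were seen, as were its tests and the families named here. Over 323 families of at least 8 genes, camera called 24 higher and 33 lower, of which 24 were also called by fry. With an estimated correlation, under which few families could pass on so few arrays, 0 were called. There, camera's adjusted p of each family named as called was 0.913. No called family changed direction under quantile normalization or median centring. Among the lower families, camera's smallest adjusted p were those of ribosomal proteins and like-named genes. They were 1.5e-06 for Mrpl, 1.8e-05 for Mrps and Rpl and 1.2e-04 for Rps, and fry called none of these (adjusted p = 0.145 to 0.206). Of 48 Mrpl genes, 6 fell and none rose. The 6 became 37 without transgenic mouse 2, 2 without transgenic mouse 1 and 0 with any other mouse left out. Of 15 aldo-keto reductases (Akr), 6 fell and none rose, among them Akr1c13 (-2.85, SE 0.17) and Akr1c12 (-2.17, SE 0.12). Of 21 aldehyde dehydrogenases (Aldh), 7 fell and none rose, led by Aldh1b1 (-3.07, SE 0.33), which became 3, 4 or 3 without control mouse 1, 2 or 3. Of 16 carboxylesterases (Ces), 6 fell and Ces2f rose (2.38, SE 0.48). Of 87 cytochromes P450 and like-named genes (Cyp), 17 fell, among them Cyp2b10 (-3.81, SE 0.63), and Cyp4b1 rose (1.96, SE 0.11); the 17 became 4, 6 or 7 without control mouse 1, 2 or 3. Of 11 glucuronosyltransferases (Ugt), 5 fell and none rose, which became 1, 3 or 1 without control mouse 1, 2 or 3, 4 without transgenic mouse 1 and 3 without transgenic mouse 3. The Sult and Hsd families were not called by camera (adjusted p = 0.818 and 0.753). The shifts of the Ces, Cyp and Ugt families were not called by camera without transgenic mouse 2, nor that of the Cyp family by fry (adjusted p = 0.222). Of 11 coenzyme Q genes (Coq), 5 fell and 1 rose, and the 5 became 2 with any 1 control mouse left out, 3 without transgenic mouse 3 and 8 without transgenic mouse 2.

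Of 24 myosins and like-named genes (Myo), 11 rose and 1 fell, with Myo1c at 2.76 (SE 0.11) and Myo1e at 1.55 (SE 0.12), and the 11 became 5 with any 1 control mouse left out and 7 without transgenic mouse 1 or 3. Of 12 integrin beta genes and relatives (Itgb), 5 rose and none fell, with the epithelial Itgb6 at 2.99 (SE 0.24) and the leukocyte integrins Itgb2 at 1.26 (SE 0.09) and Itgb7 at 0.88 (SE 0.09); 8 were higher without transgenic mouse 2. The Myh, Itga, Cdh and Cldn families were not called by camera (adjusted p = 0.277, 0.277, 0.196 and 0.175), and Itga was called by fry (0.0142). Of 8 Gimap genes, which lymphocytes express, 6 rose, with Gimap6 at 1.90 (SE 0.18), beside the rise of the T cell markers. Of 24 dual-specificity phosphatases (Dusp), which restrain MAP kinases, 8 were higher and 1 lower, with Dusp14 at 3.75 (SE 0.40) and Dusp6 at 2.42 (SE 0.19); that shift was not called without transgenic mouse 2.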
